A study of Homo sapiens with 6 samples.

How the data were processed

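Total RNA was extracted with Trizol from AGS cells, a human gastric adenocarcinoma line, transfected with siControl or siDUB1, and libraries were prepared for the BGISEQ-500 sequencer, per the labels' protocols. There were 2 groups of 3 libraries, and each sample was placed in its group by the transfection that its label names. The deposited tables held 1 row per NCBI Gene ID and a value in FPKM, per the file headers, with 2 decimals, for the same 18597 genes in each of the 6 files. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool and the annotation behind the FPKM values were not given in the sources used here, nor was the use of strand.

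FPKM divides the fragments of a gene by its length and by the mapped fragments of the library, so a rise in a few abundant genes lowers all others. The sums of FPKM were 545694, 573574 and 564636 in siControl replicates 1, 2 and 3 and 590214, 583243 and 694878 in siDUB1 replicates 1, 2 and 3. The sequencing depth is unknown. Ratios of FPKM between libraries for short, low genes (0.1 to 0.6 FPKM, transcripts shorter than 1200 nt) peaked at a log2 ratio of 0 against siControl replicate 1, and at 0.1 for siDUB1 replicate 3. This is only weak evidence of similar depths, and whole reads were not recovered. No interval that needs a depth is given.

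Gene IDs were matched to symbols and GRCh38 coordinates through a RefSeq gene table, which named 18437 of them. The other 160 kept their IDs, and 25 of these were tested. DUB1 is a synonym of USP36 and TAZ one of WWTR1 in that table, and neither was chosen by its values. Transcript GC content and length were medians over the protein-coding transcripts of a gene in GENCODE, available for 10907 tested genes (99.2%).

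A gene was tested when its FPKM was at least 1 in at least 3 of the 6 libraries, which left 10994 genes. The values were transformed to log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with all 6 libraries and no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05. An exact permutation test of 3 against 3 cannot give a p below 0.1, so the calls rest on the model's shared estimate of spread. Means and SDs are of the FPKM values of 3 libraries.

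Of 31 gene lists fixed before the data were examined, 27 had at least 5 tested members. These were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted by Benjamini-Hochberg over the 27 lists. Past the threshold were 15 lists with the preset correlation and 0 with the estimated one. Fry tests whether the members of a list move on balance one way, without comparing them with other genes, and it called the YAP/TAZ targets (adjusted p = 0.0257) but not the Hippo components (adjusted p = 0.222). The 5 lists drawn up after the results were seen were adjusted together with the 27, over 32 lists. Counts adjusted over the list alone used Benjamini-Hochberg within the list.

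The genes named were set by a rule before the data were examined. They were, first, the targeted gene, WWTR1, YAP1, CCN1, CCN2, ANKRD1 and AXL whatever their values. Next came the 10 that rose and the 10 that fell with the largest log2 change among genes past the threshold with a mean of at least 5 FPKM in the higher group and groups that did not overlap. Last came, per list, up to 2 members that rose and up to 2 that fell with the smallest adjusted p, or, where none passed, up to 2 with the smallest p. Some list members that this rule would name are not reported here. Members named beyond this rule complete a small count or a figure and were named after their values were seen, as were those of the lists and symbol families under other observations.

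Alternatives were size factors from median ratios, quantile normalization, no filter on low values, a filter of 5 FPKM, pseudocounts of 0.1 and 0.01, eBayes without the trend and with robust estimation, the replicate number as a block, and leaving out each library in turn. A correction of each library's deviation from the mean of the libraries for GC content and length, by natural splines with 4 degrees of freedom each, was added after the data were seen, with all libraries and without siDUB1 replicate 3. A first test of GC content and length for the amino acid response used the whole list of the unfolded protein and ATF4 response, whose median was -0.24 before and -0.28 after the correction, and was replaced by the amino acid arm because it could not bear on a rise. The test of single genes was tried on simulated data for the comparison of siDUB1 with siControl, with 200 of 10994 genes changed. With the spread of all 6 libraries it recovered 40% of changes of 1 and 77% of changes of 2 on the log2 scale, with 10 false calls. With the spread of the 5 libraries without siDUB1 replicate 3 it recovered 91% and 98%, with 7 false calls. The simulated spread was independent between genes and the same in every library. In the data siDUB1 replicate 3 differed from the others across many genes together, so these rates may not hold here. Values were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.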

Results

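The series measured messenger RNA in AGS, an established human gastric adenocarcinoma cell line, after transfection with a control small interfering RNA (siControl) or with one directed at DUB1 (siDUB1). A small interfering RNA is a short duplex that leads to degradation of the matching transcript. Each group held 3 libraries, and expression was given as FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for 18597 genes in each of the 6 libraries. The labels do not say whether the replicates were separate cultures, so p-values here measure only the spread between these samples, which may be technical. The number of reads per library is unknown, because the files hold FPKM values rounded to 2 decimals. FPKM was above 0 for between 15687 and 16212 genes per library.

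The transcript of the deubiquitinase USP36, taken here as the target of siDUB1, fell. Several targets of the Hippo effectors YAP and TAZ fell with it, among them ANKRD1, CCN1 and CCN2, as did the natriuretic peptide gene NPPB and cytoskeletal genes such as TAGLN. The interferon-induced gene BST2, which restrains virus release, and the hypoxia-inducible genes ANKRD37 and NDRG1 rose. In the RefSeq gene table DUB1 is a synonym of USP36 (NCBI Gene 57602, GRCh38 chromosome 17, 78787381 to 78841439), a deubiquitinase that resides largely in the nucleolus. The target rests on this synonym alone, as the sequence of the small interfering RNA is not given in the sources used here. USP36 stood at 9.16, 6.74 and 7.25 FPKM in siControl replicates 1, 2 and 3 and at 4.11, 4.75 and 2.59 FPKM in siDUB1 replicates 1, 2 and 3. The mean fell from 7.72 ± 1.28 to 3.82 ± 1.11 FPKM (SD, n = 3 in each group), a ratio of 0.495, and every siDUB1 library lay below every control library. The log2 change was -0.87 with a standard error of 0.21 (limma, adjusted p = 0.0432). This call lay close to the threshold. The adjusted p was 0.179, 0.125 and 0.152 without siControl replicate 1, 2 or 3, 0.0878 and 0.0509 without siDUB1 replicate 1 or 2, and 1.97e-04 without siDUB1 replicate 3. With pseudocounts of 0.1 and 0.01 the change was -1.03 and -1.05 and the adjusted p 0.0516 and 0.0526.

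The series title places DUB1 in Hippo signalling through TAZ, whose gene is WWTR1 (NCBI Gene 25937, chromosome 3, 149517235 to 149724788). TAZ and its paralogue YAP, from YAP1 (NCBI Gene 10413, chromosome 11, 102110447 to 102233424), are co-activators that the Hippo kinases hold back. Of the 22 genes in a list of YAP/TAZ targets, 15 could be tested, and 6 fell, none rose and 9 did not pass. ANKRD1 fell from 102 ± 1.40 to 19.1 ± 6.95 FPKM (log2 change -2.43, SE 0.27, adjusted p = 0.00578). CCN2, which encodes a secreted matrix protein also known as CTGF, fell from 57.9 ± 4.62 to 17.9 ± 6.64 FPKM (log2 change -1.71, SE 0.28, adjusted p = 0.0155). CCN1, also known as CYR61, fell from 17.8 ± 0.441 to 5.89 ± 2.24 FPKM (log2 change -1.51, SE 0.26, adjusted p = 0.0179). The kinase gene NUAK2 fell from 15.8 ± 0.462 to 5.38 ± 0.409 FPKM (log2 change -1.40, SE 0.11, adjusted p = 0.00206), all with n = 3 per group. F3, of tissue factor, and CRIM1 were the remaining members that fell, with log2 changes of -2.14 and -1.59. The receptor gene AXL averaged 6.60 and 5.16 FPKM in the control and siDUB1 groups and did not pass (adjusted p = 0.19). Adjusted over the list alone, 11 members were lower.

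The list of YAP/TAZ targets had a median log2 change of -1.07 and passed camera with a preset correlation between genes (adjusted p = 3.29e-06). That call was lost with an estimated correlation (adjusted p = 0.436 with an estimated correlation). All 15 tested members were lower without siDUB1 replicate 3, and the median was -0.66. Camera then gave an adjusted p of 3.30e-08 with the preset correlation, but 0.273 with an estimated one. Without the low-value filter the median was -0.60 (camera adjusted p = 1.28e-06 with the preset correlation). For single members calls were lost when a control library was left out. Without siControl replicate 1, 2 or 3 the limma adjusted p was 0.0923, 0.0765 and 0.0909 for CCN2 and 0.1, 0.0895 and 0.0988 for CCN1. For ANKRD1 it was 0.0532 without siControl replicate 1. The list median was -1.02, -1.09 and -1.08 in the fits without siControl replicate 1, 2 or 3. Without siDUB1 replicate 3 the limma adjusted p was 7.33e-09 for CCN2, 1.7e-08 for CCN1 and 3.93e-11 for ANKRD1.

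The transcripts of the co-activators themselves did not pass the test. WWTR1 averaged 4.43 ± 0.155 FPKM in siControl and 4.88 ± 1.45 FPKM in siDUB1 (n = 3 each, log2 change 0.08, SE 0.21, adjusted p = 0.789). YAP1 averaged 13.7 ± 1.05 and 11.8 ± 5.25 FPKM (log2 change -0.30, SE 0.34, adjusted p = 0.545). siDUB1 replicate 3 held 5.81 FPKM of YAP1 and 3.21 FPKM of WWTR1, against 14.4 and 15.4 FPKM of YAP1 and 5.61 and 5.82 FPKM of WWTR1 in siDUB1 replicates 1 and 2. With that library left out WWTR1 was higher than in the controls (log2 change 0.31, adjusted p = 0.00388), and YAP1 stood at a log2 change of 0.11 (adjusted p = 0.207).

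**Figure D1:**
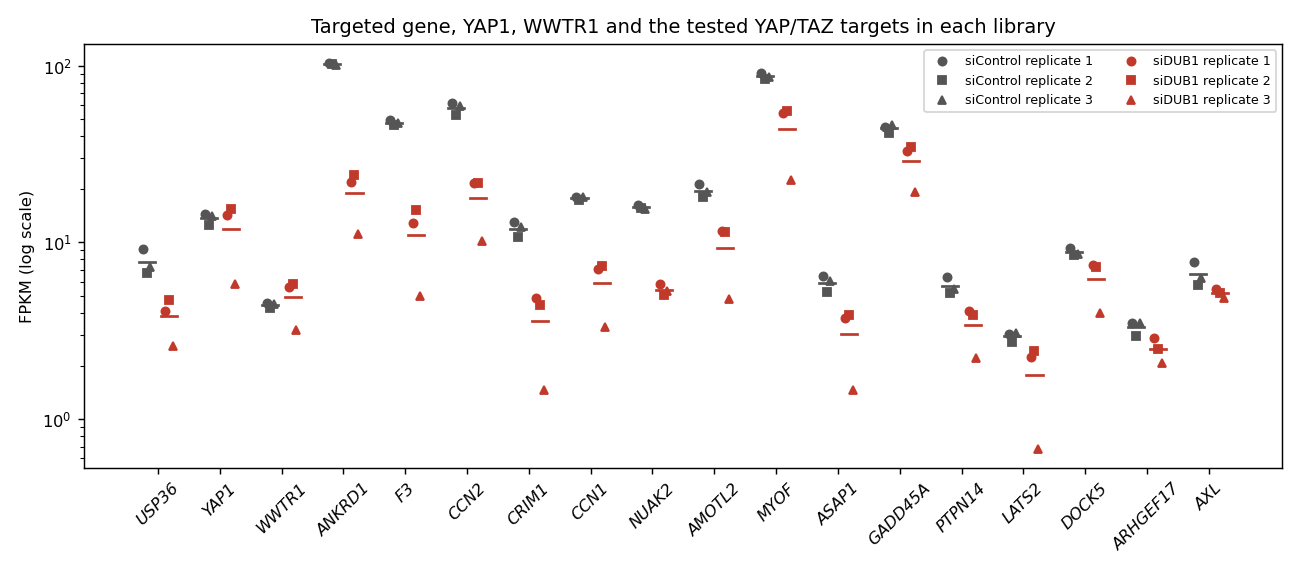
FPKM (log axis) of USP36, YAP1, WWTR1 and the 15 tested YAP/TAZ targets in each of the 6 libraries, with grey symbols for siControl, red symbols for siDUB1, a symbol shape for each replicate number and a line at each group mean. ANKRD1 averaged 102 FPKM in siControl and 19.1 FPKM in siDUB1, and siDUB1 replicate 3 (red triangles) lay lowest for every gene shown but NUAK2.

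Among 30 tested components of the Hippo pathway 3 fell, none rose and 27 did not pass. RASSF1, a scaffold of the MST kinases, fell from 13.0 ± 1.06 to 8.56 ± 0.445 FPKM (log2 change -0.55, SE 0.11, adjusted p = 0.0285). WWC2, of the KIBRA family, fell from 6.30 ± 0.703 to 2.04 ± 1.15 FPKM (log2 change -1.34, SE 0.31, adjusted p = 0.0384). FRMD6 fell by 0.74 on the log2 scale (adjusted p = 0.0421). No member passed when adjusted over the list alone. The list had a median of -0.32 and passed camera (adjusted p = 0.0135), but not with an estimated correlation (adjusted p = 0.578 with an estimated correlation). Its median was -0.14 without siDUB1 replicate 3 and the call was lost (adjusted p = 0.0603), while without siDUB1 replicate 1 or 2 the median was -0.48 and -0.50. With siDUB1 replicate 3 left out, 7 members were higher and 14 lower. That fit called 3481 of all 10994 tested genes higher and 2818 lower. The share of lower members thus lay above that over all genes and the share of higher members below it, although the list did not pass.

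Across the 10994 genes tested, 894 were higher and 651 lower in siDUB1 at an adjusted p under 0.05, of which 130 and 211 changed at least 2-fold on the log2(FPKM + 1) scale. With size factors 696 were higher and 719 lower, so the excess of higher genes depended on the scaling. The largest change was in NPPB, the gene of the natriuretic peptide BNP, which fell from 64.3 ± 3.49 to 1.47 ± 0.084 FPKM (n = 3 each), 43.9 times lower (log2 change -4.73, SE 0.11, adjusted p = 2.81e-05). Among the next largest falls MYL7, an atrial myosin light chain, fell from 81.3 to 12.2 FPKM and CFL2, the muscle cofilin, from 29.3 to 4.37 FPKM. The keratins KRT80 and KRT17 fell from 240.5 to 43.7 FPKM and from 210 to 39.4 FPKM, SERPINB2 from 25.1 to 3.85 FPKM and the transcriptional inhibitor ID2 from 89.1 to 18.2 FPKM. CGB8 and CGB5, chorionic gonadotropin beta genes, fell from 16.5 to 1.73 FPKM and from 9.59 to 0.977 FPKM. They are near-identical copies of each other, as KRT17 is of pseudogenes, so the split of reads between copies is uncertain. Of the 10 largest falls, which include ANKRD1, those of CGB8 and ID2 lost their calls without siControl replicate 1, 2 or 3, with adjusted p of 0.0572, 0.0517 and 0.0554 for CGB8 and of 0.0783, 0.0723 and 0.0765 for ID2.

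Among the 10 genes with the largest rises ANKRD37, a hypoxia-inducible gene, rose from 0.69 ± 0.095 to 9.45 ± 1.97 FPKM (log2 change 2.61, SE 0.16, adjusted p = 0.00159). The aldolase gene ALDOC rose from 5.16 to 34.1 FPKM, NDRG1 from 6.08 to 27.2 FPKM and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, from 10.5 to 43.9 FPKM. TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 3.51 to 20.3 FPKM, and DDIT4, an inhibitor of mTORC1 signalling, from 13.6 to 59.4 FPKM. LGALS4, the intestinal galectin-4, rose from 7.94 to 48.4 FPKM, BST2 from 8.25 to 37.2 FPKM, PRR15L from 5.06 to 23.5 FPKM and MIA from 1.34 to 7.61 FPKM. These 10 and the 10 with the largest falls all passed with an adjusted p of at most 0.0124.

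**Figure D2:**
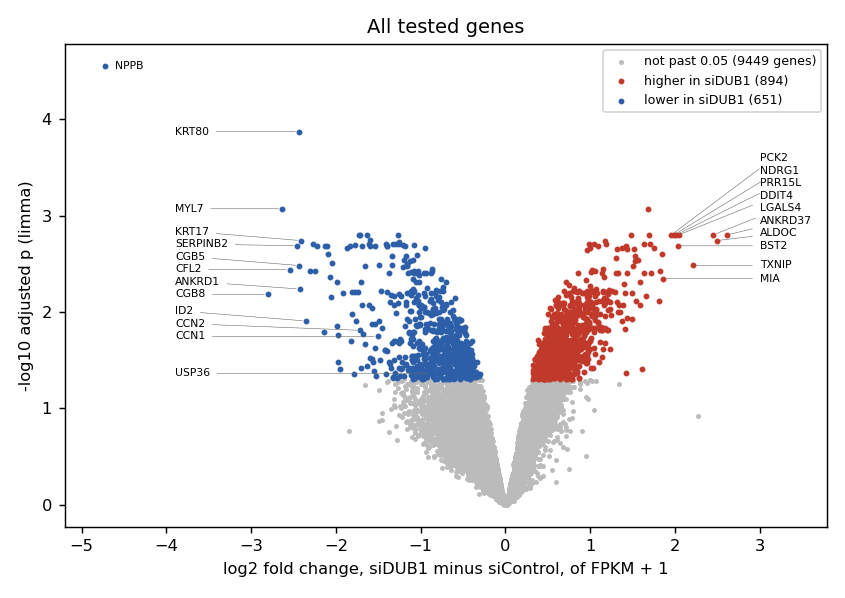
Log2 fold change of FPKM + 1, siDUB1 minus siControl, against minus log10 of the adjusted p from limma for the 10994 genes tested, with 894 higher genes in red, 651 lower genes in blue and the others in grey. NPPB stands apart at a log2 change of -4.73, and USP36 lies near the threshold at -0.87.

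The count of calls depended strongly on single libraries. It was 6299 without siDUB1 replicate 3, and those included all 894 higher and 651 lower genes with the same directions. Of the 10994 genes, 3481 were higher and 2818 lower in that fit, and counts of list members without siDUB1 replicate 3 are to be read against these shares. The count of calls was 125, 147 and 136 without siControl replicate 1, 2 or 3, and 526 and 934 without siDUB1 replicate 1 or 2. The drop was thus alike whichever control was left out, and each such fit has fewer residual degrees of freedom. In those 3 fits without a control the share of higher among all calls was 43.2%, 45.6% and 43.4%, against 57.9% with all 6 libraries. siDUB1 replicate 3 correlated with siDUB1 replicates 1 and 2 at r = 0.979 and 0.977 across genes, while the other pairs within a group lay between 0.998 and 0.999. Its median FPKM was 1.75, against 2.91 to 3.07 in the other libraries, and its 20 most abundant genes took 18.1% of the total, against 14.5% to 15.1%. Its difference from siDUB1 replicates 1 and 2 followed the GC content of transcripts, from a median of -0.86 in the tenth of genes with the lowest GC to 0.40 in the tenth with the highest, so gene groups are also given without it.

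**Figure D3:**
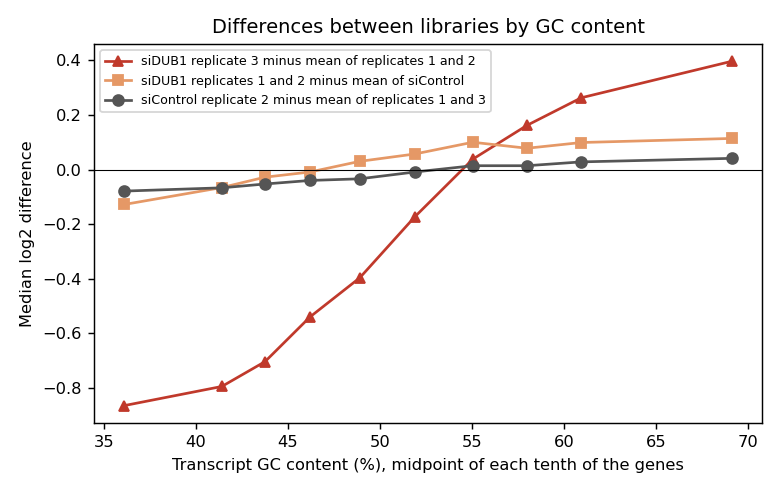
Median log2 difference against transcript GC content, in 10 bins of equal gene number, for siDUB1 replicate 3 minus siDUB1 replicates 1 and 2, for these 2 minus the controls, and for siControl replicate 2 minus siControl replicates 1 and 3. In the bin with the highest GC the medians were 0.40, 0.11 and 0.04.

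Of 29 tested genes of the interferon response 14 rose, 1 fell and 14 did not pass, with a median log2 change of 0.57 (camera adjusted p = 4.25e-07). BST2, whose product holds budding virus at the cell surface, rose 4.51-fold (adjusted p = 0.00206), and OAS2, a sensor enzyme for double-stranded RNA, rose from 1.15 to 5.11 FPKM (adjusted p = 0.0033). IRF1, an interferon-induced transcription factor, fell from 22.8 to 16.5 FPKM (adjusted p = 0.0291). Adjusted over the list alone 15 members were higher and 1 lower, and the group call was lost with an estimated correlation (adjusted p = 0.164 with an estimated correlation). The median was 0.76 without siDUB1 replicate 3, with 25 members higher and 1 lower. The list was fixed as a technical one, as small interfering RNA can itself draw such a response. With siDUB1 compared only with siControl, a response to the duplex cannot be told apart from an effect of less USP36. The same limit holds for the other genes and lists.

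Of the genes of hypoxia and glycolysis 8 of 28 tested members rose, 1 fell and 19 did not pass, with a median of 0.34 (camera adjusted p = 2.07e-04, adjusted p = 0.164 with an estimated correlation). ANKRD37 and NDRG1 had the smallest adjusted p of those that rose (both 0.00159), and the glucose transporter gene SLC2A3 fell from 161 to 38.9 FPKM (adjusted p = 0.00313). Adjusted over the list alone the counts were 11 higher and 1 lower, and without siDUB1 replicate 3 they were 19 higher and 3 lower with a median of 0.46. Cytosolic ribosomal protein genes had a median of 0.38 (camera adjusted p = 8.93e-10, adjusted p = 0.505 with an estimated correlation). That call was also lost with fry (adjusted p = 0.107). Only 4 of 64 rose singly, namely RPL3, RPL12, RPL27 and RPL4, and none adjusted over the list alone. RPL3 rose from 1042 to 1711 FPKM (adjusted p = 0.0252) and RPL12 from 1288 to 2291 FPKM (adjusted p = 0.0333). Nuclear genes of oxidative phosphorylation had a median of 0.30 (camera adjusted p = 2.98e-05, adjusted p = 0.431 with an estimated correlation), with 3 of 39 higher, or 2 adjusted over the list alone. Among them SDHB, of succinate dehydrogenase, rose from 117 to 157 FPKM, and NDUFV2 rose too. Leaving out siDUB1 replicate 3, the medians of these last 2 lists were 0.24 and 0.18, with 43 and 24 members higher and none lower, and with quantile normalization 0.14 and 0.19. With the GC and length correction and without siDUB1 replicate 3 they shrank to 0.165 and 0.091 (camera adjusted p = 3.57e-04 and 0.00229).

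Of 19 tested inflammatory genes under NF-kB control 9 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone, and the median was -0.47 (camera adjusted p = 2.85e-04, adjusted p = 0.372 with an estimated correlation). The NF-kB inhibitor gene TNFAIP3 fell from 9.68 ± 0.813 to 1.61 ± 0.652 FPKM (adjusted p = 0.0043), and BIRC3, an inhibitor of apoptosis, from 4.07 to 0.577 FPKM (adjusted p = 0.00208), while IER3 rose from 176 to 289 FPKM (adjusted p = 0.0112). The counts were 11 lower and 3 higher without siDUB1 replicate 3, with a median of -0.44.

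Targets of TGF-beta and BMP signalling were lower in 7 of 21 tested members and higher in none, with a median of -0.78 (camera adjusted p = 2.07e-04, adjusted p = 0.436 with an estimated correlation). ID1 fell from 386 ± 11.2 to 160 ± 5.88 FPKM (adjusted p = 0.00159). Mesenchymal genes were lower in 7 of 15 tested members and higher in 1, with a median of -0.72 (camera adjusted p = 1.52e-04, adjusted p = 0.164 with an estimated correlation). The actin-binding gene TAGLN fell from 341 to 81.0 FPKM (adjusted p = 0.00253), and the smooth muscle actin gene ACTA2 rose from 6.94 to 10.3 FPKM (adjusted p = 0.0295). Adjusted over the list alone 10 TGF-beta targets and 8 mesenchymal genes were lower, with 0 and 1 higher. In the fit without siDUB1 replicate 3 the medians were -0.41 and -0.30, with 13 and 11 members lower and 3 and 1 higher. The low-value filter mattered too: without it the medians were -0.40 and -0.07 (adjusted p = 5.89e-05 and 0.0111).

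Genes of the G1/S transition were lower in 7 of 38 tested members, 8 adjusted over the list alone, and higher in none (median -0.38, camera adjusted p = 2.98e-05, adjusted p = 0.436 with an estimated correlation). CCND1, the gene of cyclin D1, fell from 295 ± 16.2 to 133 ± 17.02 FPKM (adjusted p = 0.00399) and CCNE1, of cyclin E1, from 50.4 to 36.3 FPKM (adjusted p = 0.0174). Targets of p53 were lower in 3 of 27, SESN2 and PLK2 among them, and in 9 adjusted over the list alone (median -0.42, camera adjusted p = 0.00499, adjusted p = 0.436 with an estimated correlation). SESN2, a stress-induced regulator of mTORC1, fell from 32.1 to 23.8 FPKM (adjusted p = 0.031). Without siDUB1 replicate 3 the G1/S list had 24 lower and 2 higher with a median of -0.21, and the p53 list 16 lower and 2 higher with a median of -0.28, and with all 6 libraries but no low-value filter the p53 median was -0.27. Genes of G2/M did not pass as a list (median -0.09, camera adjusted p = 0.927). Of 38 tested, PTTG1 rose from 148 to 192 FPKM and CDC25C from 7.49 to 11.8 FPKM, neither when adjusted over the list alone, and without siDUB1 replicate 3 the median was 0.11 with 16 higher and 5 lower.

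Epithelial junction and keratin genes were lower in 3 of 26 tested members, KRT7, OVOL1 and CLDN1, and higher in CLDN7 alone, with the same counts adjusted over the list alone (median -0.26, camera adjusted p = 0.0311, adjusted p = 0.431 with an estimated correlation). KRT7 fell from 29.8 to 7.55 FPKM (adjusted p = 0.00218), OVOL1 from 9.66 to 6.48 FPKM (adjusted p = 0.0476), and the claudin gene CLDN7 rose from 209 to 303 FPKM (adjusted p = 0.0284). The list's adjusted p was 0.0528 without siDUB1 replicate 1 (median -0.42) and 0.0486 without siDUB1 replicate 2 (median -0.46), and without siDUB1 replicate 3 the counts were 16 lower and 3 higher with a median of -0.20. With all 6 libraries but no low-value filter that median was -0.16. Heat shock genes had a median of -0.30 (camera adjusted p = 0.046, adjusted p = 0.505 with an estimated correlation), and 1 of 18, the small heat shock protein gene HSPB8, fell, from 104 to 42.9 FPKM (adjusted p = 0.00195), also adjusted over the list alone. That list call was lost with size factors (adjusted p = 0.0629), with a stricter filter (0.0513), without the mean-variance trend (0.0501), without siControl replicate 2 (0.0623) and without siDUB1 replicate 1 or 2 (0.0627 for both), and without siDUB1 replicate 3 the median was -0.17 with 10 lower and 2 higher, against -0.47 with quantile normalization.

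Markers of gastric mucosa were higher in 2 of 5 tested members, and 3 higher and 1 lower adjusted over the list alone (median 0.72, camera adjusted p = 0.0351, adjusted p = 0.372 with an estimated correlation). MUC1, a membrane mucin, rose from 50.4 ± 3.17 to 161 ± 36.8 FPKM (adjusted p = 0.00393) and PGC, of pepsinogen C, from 0.577 to 2.01 FPKM (adjusted p = 0.00837). The summed FPKM of gastric markers did not rise. It was 716, 712 and 713 in siControl replicates 1, 2 and 3 and 687, 708 and 610 in siDUB1 replicates 1, 2 and 3. The list's camera adjusted p was 0.0523 and 0.0585 without siDUB1 replicate 2 or 3 and 0.0545 without a filter (median 0.02). With the GC and length correction it was 0.106, although the median, 0.76, was no smaller. Without siDUB1 replicate 3 the median was 0.93 with 4 higher and 1 lower. Intestinal markers were higher in 4 of 9 tested members and lower in 1, with the same counts adjusted over the list alone (median 0.42, camera adjusted p = 0.046, adjusted p = 0.372 with an estimated correlation). LGALS4 rose 6.10-fold (adjusted p = 0.00159) and REG4 from 28.0 to 64.4 FPKM (adjusted p = 0.0072), CDX2 and ALPI rose too, and VIL1, of the microvillus protein villin, fell from 84.9 to 45.6 FPKM (adjusted p = 0.00393). The intestinal call was lost with size factors (adjusted p = 0.0629), with quantile normalization (0.0754), with a stricter filter (0.227, median 0.14), without the mean-variance trend (0.0501, median 0.42), with the GC and length correction (0.125, median 0.33), without siControl replicate 2 (0.0578) and without siDUB1 replicate 1 or 2 (0.0528 and 0.0635), and without siDUB1 replicate 3 its median was 0.38 with 6 higher and 1 lower, against 0.09 without a filter. Only 2 of 18 leukocyte markers were expressed highly enough to test, and both rose: LYZ, of lysozyme, which gastric glands also make, from 186 to 542 FPKM (adjusted p = 0.0119) and CD68 from 7.38 to 17.8 FPKM (adjusted p = 0.0043). Of 2 tested markers of fibroblasts and endothelium, COL1A1 fell from 19.1 to 9.60 FPKM (adjusted p = 0.0101) and the other did not pass.

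**Figure D4:**
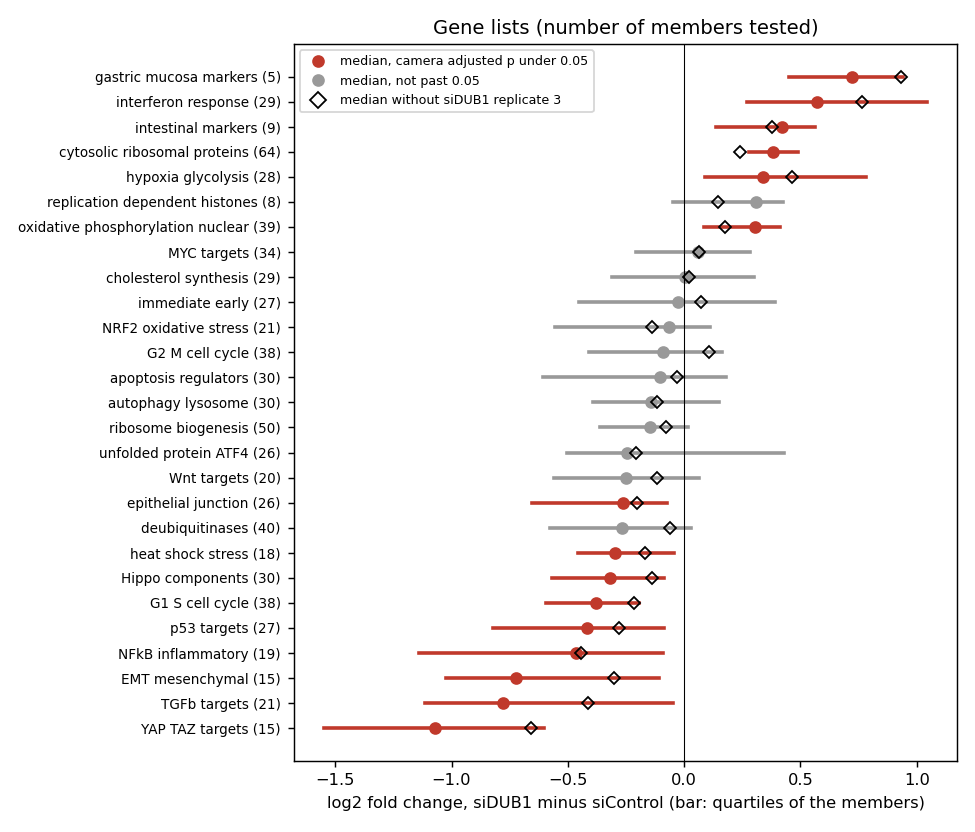
Median log2 fold change, siDUB1 minus siControl, of the 27 tested gene lists with bars from the lower to the upper quartile of the members, in red where camera with a preset correlation gave an adjusted p under 0.05, and open diamonds for the median without siDUB1 replicate 3. The YAP/TAZ targets lie lowest at -1.07, or -0.66 without siDUB1 replicate 3, and the median of G2/M genes changes sign without that library.

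The other lists did not pass camera as groups, although some members changed. Of 26 tested genes of the unfolded protein and ATF4 response 6 rose and 3 fell, or 8 and 7 adjusted over the list alone (median -0.24, mean 0.04, camera adjusted p = 0.739 in the upward direction). The asparagine synthetase gene ASNS rose from 18.9 ± 0.167 to 62.7 ± 1.87 FPKM (adjusted p = 8.51e-04) and DDIT4 rose 4.38-fold, while ATF3 fell from 43.1 to 23.7 FPKM (adjusted p = 0.0317). NRF2 targets had 2 higher and 5 lower of 21, or 5 and 5 adjusted over the list alone (median -0.07, camera adjusted p = 0.639). HMOX1, of heme oxygenase, fell from 121 to 41.5 FPKM (adjusted p = 0.00206) and OSGIN1 from 20.3 to 11.7 FPKM, while the cystine transporter gene SLC7A11 rose from 1.10 to 2.18 FPKM (adjusted p = 0.025) and ABCC3 from 11.2 to 16.9 FPKM. Immediate early genes had 4 higher and 4 lower of 27, or 5 and 6 adjusted over the list alone (median -0.03, camera adjusted p = 0.891). IER2 rose from 54.3 to 75.9 FPKM, as did IER3, ETV4 and EGR1, and the phosphatase genes DUSP1 and DUSP4 fell from 17.4 to 4.37 FPKM and from 121 to 65.4 FPKM, as did ATF3 and KLF4. Leaving out siDUB1 replicate 3, the medians of these 3 lists were -0.20, -0.14 and 0.07, with 11, 5 and 10 higher and 14, 10 and 9 lower.

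Apoptosis regulators had 4 higher and 3 lower of 30, or 4 and 9 adjusted over the list alone (median -0.10, camera adjusted p = 0.592). BCL2L1, of BCL-XL, rose from 257 to 357 FPKM, as did TRADD, BAK1 and CASP9, and CYCS, of cytochrome c, fell from 24.4 to 11.1 FPKM, as did BIRC3. Wnt targets had 2 higher and 3 lower of 20, or 3 and 4 adjusted over the list alone (median -0.25, camera adjusted p = 0.30). SP5 rose from 56.3 to 141 FPKM and BMP4 from 12.3 to 26.0 FPKM, while CCND1, EPHB3 and SOX4 fell. MYC targets had 4 higher, SHMT2, SHMT1, TRAP1 and CAD, and 3 lower, ODC1, MCM4 and TMEM97, of 34, or 5 and 3 adjusted over the list alone (median 0.06, camera adjusted p = 0.30). SHMT2 rose from 78.0 to 115 FPKM and ODC1 fell from 120 to 87.6 FPKM. Among 50 genes of ribosome biogenesis, which takes place in the nucleolus, NAT10 rose from 21.2 to 27.8 FPKM (adjusted p = 0.0362), but not adjusted over the list alone (median -0.15, camera adjusted p = 0.243). Leaving out siDUB1 replicate 3, the medians of these 4 lists were -0.03, -0.12, 0.07 and -0.08, with 8, 5, 13 and 8 higher and 11, 8, 6 and 19 lower.

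Of 40 deubiquitinase genes USP36 fell and USP21 rose, from 13.6 to 22.8 FPKM (adjusted p = 0.0239), neither adjusted over the list alone (median -0.27, camera adjusted p = 0.150). The list of cholesterol synthesis had 3 higher of 29, FDFT1, FDPS and FADS2, of which FADS2 encodes a fatty acid desaturase. The count was the same adjusted over the list alone (median 0.00, mean -0.05, camera adjusted p = 0.472 in the upward direction). Autophagy and lysosome genes had 1 higher, WIPI2, and 2 lower of 30, with 0 higher and 2 lower adjusted over the list alone (median -0.14, camera adjusted p = 0.390). The autophagy receptor gene SQSTM1 fell from 255 to 157 FPKM (adjusted p = 0.00486), and GABARAPL1 from 15.9 to 9.72 FPKM (adjusted p = 0.0242). No replication-dependent histone gene of 8 passed, with 3 higher adjusted over the list alone (median 0.31, camera adjusted p = 0.116). H2AC20 averaged 7.16 and 11.6 FPKM in the control and siDUB1 groups, and without siDUB1 replicate 2 the histone list passed (median 0.35, adjusted p = 0.0498). None of 4 tested transcripts that host small nucleolar RNAs passed, and 1 was higher adjusted over the list alone (median -0.02). EEF2, of a translation elongation factor, averaged 760 and 978 FPKM (adjusted p = 0.0675). With siDUB1 replicate 3 left out, 9, 11, 7, 3 and 2 members of these 5 lists were higher and 15, 7, 12, 1 and 0 lower, with medians of -0.06, 0.02, -0.12, 0.15 and 0.16. The list of genes encoded by the mitochondrial genome was not analysed here, as none of its 13 members had values.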

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

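The corrections for GC content and length were chosen after the data were seen, and the other alternatives before. The 1545 genes past the threshold became 2554 (1364 higher, 1190 lower) with quantile normalization, 3485 (1861 and 1624) with the GC and length correction, 6381 (3307 and 3074) with that correction without siDUB1 replicate 3, and 125 to 6299 (54 to 3481 higher, 71 to 2818 lower) when a library was left out. siDUB1 replicate 3 was the library whose absence raised the count. Whether the replicate numbers pair the samples could not be decided. The correlations of deviations were 0.25, -0.49 and -0.23 for numbers 1, 2 and 3, and not every sample correlated best with its own number. However, siDUB1 replicates 1 and 2 correlated alike with each control and siDUB1 replicate 3 the other way (-0.46, -0.49 and 0.50 with siControl replicate 2). The distance of siDUB1 replicate 3 thus dominates these values and could hide a pairing. With the replicate number as a block 179 genes passed (81 higher, 98 lower), a fit with fewer residual degrees of freedom. The 130 genes higher by at least 2-fold became 223 and 235 with pseudocounts of 0.1 and 0.01, by construction, 76 with the block and 49 to 169 when a library was left out; the 211 lower became 89 with the block and 63 to 209. USP36 stayed lower throughout. Its change was -0.87 without a filter (adjusted p = 0.0676) and with the block (0.0985), -1.03 and -1.05 with pseudocounts of 0.1 and 0.01, and -1.01 to -0.68 when a library was left out. The YAP/TAZ targets kept their call under all alternatives but the estimated correlation (median -1.07, adjusted p = 0.436). Hippo components lost it with the estimated correlation and with fry (median -0.32 for both), with the GC and length correction without siDUB1 replicate 3 (-0.13) and without that library (-0.14, over a range of -0.50 to -0.14). Of the other lists 13 passed, 10 to 14 under the other settings, 15 with fry and 0 with the estimated correlation. Counted over 27 lists and 19 alternatives, 457 of 512 list results kept direction and side, 39 lost the call, 5 gained it and 11 changed the sign of their median. Of 1488 results of single named genes 1202 kept both, 266 lost the call, 15 gained it and 5 changed sign. The G2/M list ran from -0.18 to 0.11 when a library was left out, with 0.11 without siDUB1 replicate 3, and had 0.10 with the GC and length correction and 0.13 with both (adjusted p = 0.0258). Immediate early genes had 0.043 with size factors and -0.083 to 0.072 when a library was left out, cholesterol genes -0.018 to 0.043, and NRF2 targets 0.003 with size factors and -0.139 to 0.025. With the GC and length correction and without siDUB1 replicate 3 the NRF2 targets passed camera (median -0.132, adjusted p = 0.0278). WWTR1 stood at -0.11 with the GC and length correction and at -0.04 to 0.31 when a library was left out, and YAP1 at 0.16 with the correction without siDUB1 replicate 3 and at -0.52 to 0.11. Where no reason is given, the cause was not tested. Restricting the test to genes listed in all 6 files changes nothing, since each file lists the same genes. Depth limits the low genes, but how far is unknown.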

Other observations

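The SRF list and the tests of GC content and length, of other cell types, of the YAP/TAZ targets and of the chaperone arm were chosen only after the results were seen, while the test of the synthetases was set after the main test but before they were looked at. Many genes of the contractile cytoskeleton outside the YAP/TAZ list were lower in siDUB1. In a list of 23 tested targets of SRF, the serum response factor, and of actin dynamics, none of them in the YAP/TAZ list, 15 fell and 1, ACTA2, rose, or 18 and 2 without siDUB1 replicate 3. The camera call of this list was lost with an estimated correlation (adjusted p = 0.0986). CNN1, of calponin, fell from 2.48 to 0.117 FPKM (adjusted p = 0.00159), MYH9, of non-muscle myosin heavy chain, from 120 to 57.6 FPKM (adjusted p = 0.00256), MYL9 from 455 to 205 FPKM (adjusted p = 0.0141), VCL, of vinculin, from 94.2 to 44.9 FPKM (adjusted p = 0.0399) and ACTG1, of cytoplasmic actin gamma, from 2506 to 1312 FPKM (adjusted p = 0.0149). SRF itself fell from 46.4 to 23.7 FPKM (adjusted p = 0.00691). Keratins fell with them, 9 of 16 tested and none higher. KRT81 fell from 73.4 to 14.6 FPKM (adjusted p = 0.00195), KRT6A from 4.58 to 1.21 FPKM and KRT13 from 11.6 to 4.87 FPKM, although KRT81 and KRT86 share near-identical sequence. Among dual-specificity phosphatases 6 of 15 fell and none rose, with DUSP3 falling from 20.1 to 10.99 FPKM. Among interleukins and their receptors 10 of 26 fell, with IL32 from 413 to 138 FPKM (adjusted p = 0.00837) and IL6ST, of the receptor subunit gp130, from 6.34 to 1.67 FPKM (adjusted p = 0.0239), and IL17RE rose.

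Transcripts of cytosolic tRNA synthetases, which charge tRNAs with amino acids, were higher in 8 of 20 tested members and lower in none (adjusted p = 0.116 with an estimated correlation), or 16 and 2 without siDUB1 replicate 3. AARS1 rose from 39.9 to 65.1 FPKM (adjusted p = 0.00609), CARS1 from 20.5 to 33.9 FPKM (adjusted p = 0.00815) and KARS1 from 81.2 to 122 FPKM (adjusted p = 0.00754). Among mitochondrial synthetases TARS2 rose from 19.0 to 35.3 FPKM (adjusted p = 0.00609) and PARS2 from 5.19 to 7.90 FPKM, of 17 tested. Of 16 genes of intraflagellar transport, the traffic inside cilia, 7 rose and none fell, with IFT27 from 10.2 to 22.6 FPKM (adjusted p = 0.00957) and IFT140 from 1.89 to 4.30 FPKM (adjusted p = 0.0195), but the family did not pass camera (median 0.26, adjusted p = 0.0544). It passed without siDUB1 replicate 3 (median 0.33, adjusted p = 0.0422) and with the GC and length correction (median 0.45, adjusted p = 0.0126). Of 133 families of gene symbols with at least 10 tested members, 10 passed camera with the preset correlation, and 6 of these passed after the GC and length correction as well. Chance among families stays open, because no family passed camera with an estimated correlation (adjusted p = 0.976 with an estimated correlation). The preset correlation also passed 4 to 10 gene lists in splits that mix the groups. Those splits keep part of the difference between the groups, so they give no rate of false calls. The 10 were the keratins (median -0.92), interleukins (-0.35), dual-specificity phosphatases (-0.42), large and small cytosolic ribosomal proteins (0.41 and 0.32), large and small mitochondrial ribosomal proteins (0.19 and 0.20), DHRS (0.38), NUDT (0.28) and SMIM (0.27) genes, with the same signs under size factors and quantile normalization. With quantile normalization the medians shrank to 0.19 and 0.11 for large and small cytosolic and to 0.11 for large mitochondrial ribosomal proteins. Those of DHRS, NUDT and SMIM genes were larger, at 0.45, 0.34 and 0.40. Without siDUB1 replicate 3 only the keratins, the interleukins and the large cytosolic ribosomal proteins still passed (adjusted p = 1.11e-05, 0.0192 and 1.19e-05). The GC and length correction took the calls of small cytosolic, large and small mitochondrial ribosomal protein and DHRS genes (camera adjusted p = 0.0939, 0.0876, 0.0857 and 0.0975).

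siDUB1 replicate 3 stood apart from siDUB1 replicates 1 and 2. RNA of leukocytes, fibroblasts or endothelial cells is argued against, and other cell types were not tested: the summed FPKM of 29 leukocyte, fibroblast and endothelial markers that were low in the controls was 3.39, or 0.88 times the highest of the other libraries (3.84), a test that replaced a first sum over all markers dominated by LYZ. GC content and transcript length explained 52.5% of the variance across genes of its difference from replicates 1 and 2, against 11.1% to 14% for the control libraries, and the median difference ran from -0.86 in the tenth of genes with the lowest GC to 0.40 in the tenth with the highest. A stronger response stays open: after the correction its changes were 1.05 times those of replicates 1 and 2 (95% interval 1.01 to 1.09, 242 genes), but the genes were chosen by their change in these replicates and both sides share the controls, so this slope decides nothing. A GC-dependent bias of this library may therefore account for much of its distance, and what produced that bias stays open.

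Of the transcripts of YAP1 and WWTR1, which did not pass, 0 of 2 lay below every control library in both siDUB1 replicates 1 and 2, where all 15 YAP/TAZ targets were lower, although both did in siDUB1 replicate 3 (5.81 and 3.21 FPKM). GC content and length are argued against as the whole cause, since the median of the list was -0.80 after the correction (camera adjusted p = 3.60e-07) and -0.59 with the correction and without siDUB1 replicate 3. A general fall of SRF and actin target transcripts, many of which share regulators with YAP/TAZ targets, stays open, with a median of -0.81 for that list (camera adjusted p = 1.08e-07, adjusted p = 0.0986 with an estimated correlation). The fall of YAP/TAZ targets may thus be part of a wider loss of cytoskeletal transcription, or the reverse. Whether less TAZ protein accounts for it, as the series title implies, was not tested by transcript levels.

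Of 15 tested genes of the amino acid response 6 rose, 2 fell and 7 did not pass. Those that rose include ASNS, CHAC1 (16.8 to 64.1 FPKM) and ATF4 (285 to 377 FPKM). In the whole list of the unfolded protein and ATF4 response, SESN2 and ATF3 fell (log2 changes -0.42 and -0.87, limma adjusted p = 0.031 and 0.0317). General endoplasmic reticulum stress would raise the chaperone arm, which moved the other way (median -0.51, quartiles -0.68 to -0.41, camera adjusted p = 0.0142). Only 1 of 11 members passed, and the call was lost with an estimated correlation (adjusted p = 0.445 with an estimated correlation). Without siDUB1 replicate 3, 10 of 11 were lower and 1 higher. The arms were drawn up after the results were seen, so this is only weak evidence against such stress. A programme of ATF4 may account for those that rose, and the test of cytosolic tRNA synthetases went with it (median 0.32, camera adjusted p = 1.72e-04), but that call was lost with an estimated correlation in every setting. GC content and length cannot be told apart in full: the median was 0.40 (quartiles -0.24 to 0.57) before the correction and 0.30 (-0.14 to 0.93) after it, and the call was lost (camera adjusted p = 0.0109 and 0.0919), while with the correction and without siDUB1 replicate 3 it was 0.38 (adjusted p = 0.012). With an estimated correlation no setting passed (adjusted p = 0.268 before the correction, 0.235 after it and 0.148 without that library as well).

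With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1545 genes past the threshold, 894 higher and 651 lower, and was 1 of 10 to give as many of each, with 0 as the highest of the other splits. It gave 15 gene lists past the threshold, against 4 to 10 in the others, which was again 1 of 10. The other splits put libraries of both groups on each side, so a difference between the groups widens their spread. Part of that difference also stays between their sides. The contrasts with 0 genes and with 4 to 10 lists therefore decide nothing.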
